A study of Arabidopsis thaliana with 12 samples.

How the data were processed

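The series comprised 12 messenger RNA libraries from Arabidopsis thaliana Col-0 seeds, 3 each of dry wild-type, stratified wild-type, dry mutant-labelled and stratified mutant-labelled seeds. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected on oligo-dT beads, and libraries were made with a directional kit, and stratified seeds were held in water at 4 °C. The submitters' processing notes name STAR, DESeq2 and the genome build TAIR10, without versions or roles. The counting program, its use of strand and the treatment of reads that map to several genes are not given in the sources used here.

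The authors deposited a table of RPKM values for 32833 loci in the 12 libraries, of which 8657 were at 0 in every library. RPKM divides the reads of a locus by its length and by the reads of the library, so a few very abundant transcripts, or ribosomal RNA, lower the value of every other gene in that library. The reference used here for names, positions and exon lengths was the TAIR10.1 assembly with its RefSeq annotation, in which 32548 loci of the table were found. With the exon-union length of each locus, the steps between values under 2 RPKM gave the worth of 1 read. Of 60781 low values 99.37% came out as whole reads within 0.05 reads, where 10% would by chance. The reads in the RPKM denominator were 22.0, 22.6 and 18.6 M for wild-type dry libraries 1, 2 and 3, 23.0, 21.4 and 22.5 M for wild-type stratified, 17.8, 18.3 and 18.7 M for mutant-labelled dry, and 22.8, 21.8 and 22.1 M for mutant-labelled stratified libraries. Reads recovered for the loci of the table made up 67.5% to 90.2% of these totals. A floor of 3 reads per library was used where a group was at 0. Folds above a floor are those of the mean of the higher group, so single libraries can lie lower. Floors cover counting error only, since reads carried no molecular identifiers.

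Replicates were compared before they were averaged. The chi-square per degree of freedom of the reads of replicate pairs ran from 3.28 to 525, so no pair agreed within sampling noise and no library was counted as a repeat deposit of another. Because the deposited values are RPKM, a count test was not used. Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, in one fit of 4 group means over all 12 libraries with a mean-variance trend and 8 residual degrees of freedom. Genes with at least 1 RPKM in at least 3 libraries were kept, 15145 in all. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. The 5 contrasts were stratification in each genotype, genotype in dry and in stratified seeds, and the interaction, which tests whether the response to stratification differs between genotypes. Tests were 2-sided and p-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, with a threshold of 0.05.

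Before the data were examined, 17 gene lists with 318 members were fixed, and 8 members whose locus carries another name in the reference were dropped. Of the lists, 15 had at least 3 tested members and were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Camera compares a list with all other genes. Its direction was down while the list median was above 0 for ABA metabolism, ABA signalling, cold response and methylation after stratification in both genotypes, and for dormancy, oil mobilisation and photosynthesis in mutant-labelled seeds. It was up while the median was below 0 for storage, LEA and heat shock genes between genotypes in dry seeds, for ABA signalling and cold response in stratified seeds, and for gibberellin in the interaction. Median and mean differed in sign for DNA replication in dry seeds and methylation in the interaction. With an estimated correlation no list was called in any contrast. Fry, which tests whether a list moves on balance one way and compares it with no other genes, called none in the genotype contrasts or the interaction. The estimated correlation within the lists ran from 0.297 for ABA metabolism to 0.951 for ribosomal proteins.

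Genes were named by a rule fixed beforehand: the ALKBH1A and ALKBH1B loci; per contrast the 6 genes with the highest and the 6 with the lowest log2 change among those passing, changed at least 2-fold, without overlap between libraries and with a mean of at least 5 RPKM in the higher group; a set of regulators whatever their result; and up to 2 passing members per list and direction. For the interaction, overlap between libraries was not considered and the mean of at least 5 RPKM could be in any group. Members of families with near-identical copies, among them the Rubisco small subunit, ribosomal protein, seed storage albumin and small heat shock protein genes, are uncertain because reads could be split between copies.

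The fit was tested on simulated data, with log2 values drawn independently for the real genes. They were drawn around the mean of each gene over all 12 libraries, with the spread of dry or of stratified libraries. Unchanged genes thus had no difference between dry and stratified seeds, and 200 genes were changed by known amounts. At a log2 change of 1 it recovered 37% of changed genes for stratification in wild type, 30% for stratification in mutant-labelled seeds, 29% for genotype in dry seeds, 39% for genotype in stratified seeds and 9% for the interaction. At a log2 change of 2 it recovered 89%, 92%, 90%, 87% and 61%. False calls numbered 9, 20, 1, 157 and 15 among the 15145 genes in that order. The fit pools the spread between replicates over dry and stratified libraries. Fits of the groups compared alone gave 2, 11, 7 and 2 false calls for the first 4 contrasts and recovered 74%, 79%, 99% and 33% at a log2 change of 2. A simulated rise of the ribosomal protein list by a log2 of 1 was called, with 0 other lists. The simulated genes were independent, whereas the estimated correlation within this list was 0.951. That simulation therefore does not show how often lists of correlated genes are called falsely.

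Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 RPKM, median centring, TMM-style scaling, quantile normalization, fits of the groups compared alone, a robust variance model, a model without trend, the replicate number as a block and each library left out. Chosen after seeing the data were removal of ribosomal RNA with rescaling, voom on recovered reads of 15017 genes, omission of the 4 libraries with over 10% of reads from ribosomal RNA, omission of both stratified libraries numbered 3, ribosomal RNA over 10% as a factor, and stratified libraries under or over 10% alone. Positions are 1-based. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.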

Results

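Messenger RNA was measured in seeds of Arabidopsis thaliana, ecotype Col-0, of the wild type and of a line labelled as mutant in AtALKBH1A and AtALKBH1B. The series title describes these genes as demethylases of N6-methyladenine in DNA. Seeds of each genotype were sampled dry and after 2 days of stratification, a cold treatment in water at 4 °C that releases dormancy, with 3 libraries in each of the 4 groups. No group was held in water without cold, so changes after stratification cannot be divided between cold, water uptake and time. The deposited values were RPKM, reads scaled by the length of the transcript and by the reads of the library. The steps between low values placed the number of reads behind each library at up to 23.0 M. The labels did not say whether replicates came from separate plants or seed batches. The p-values therefore measure the spread between these samples, which may be technical. In the main fit that spread is pooled over dry and stratified libraries.

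Stratified libraries of one genotype correlated with each other at r from 0.890 to 0.991, and dry libraries of one genotype at 0.990 to 0.996. The first principal component of log2(RPKM + 1) held 83.6% of the variance and placed the dry libraries between -96.7 and -89.2, wild-type stratified libraries 1, 2 and 3 at 127, 143 and 71.5, and mutant-labelled stratified libraries 1 and 2 at 85.2 and 76.4, with library 3 below both. Wild-type stratified library 3 correlated across genes at r = 0.916 and 0.890 with libraries 1 and 2 of its own group, and at 0.985, 0.953 and 0.980 with the mutant-labelled stratified libraries 1, 2 and 3. Nuclear ribosomal RNA, which poly(A) selection should largely remove, took 15.4% of reads in wild-type stratified library 3, 15.1% and 29.3% in mutant-labelled stratified libraries 1 and 3, and 10.8% in mutant-labelled dry library 2. The other 8 libraries lay between 3.05% and 5.91%. The 10 highest loci held 37.7% to 42.2% of summed RPKM in dry libraries, 13.4%, 8.66% and 33.1% in wild-type stratified libraries 1, 2 and 3, and 27.5%, 16.9% and 47.2% in mutant-labelled ones. Plastid loci held 0.133% to 1.87% and mitochondrial loci 0.110% to 1.53% of summed RPKM, both highest in mutant-labelled stratified library 3.

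**Figure D1:**
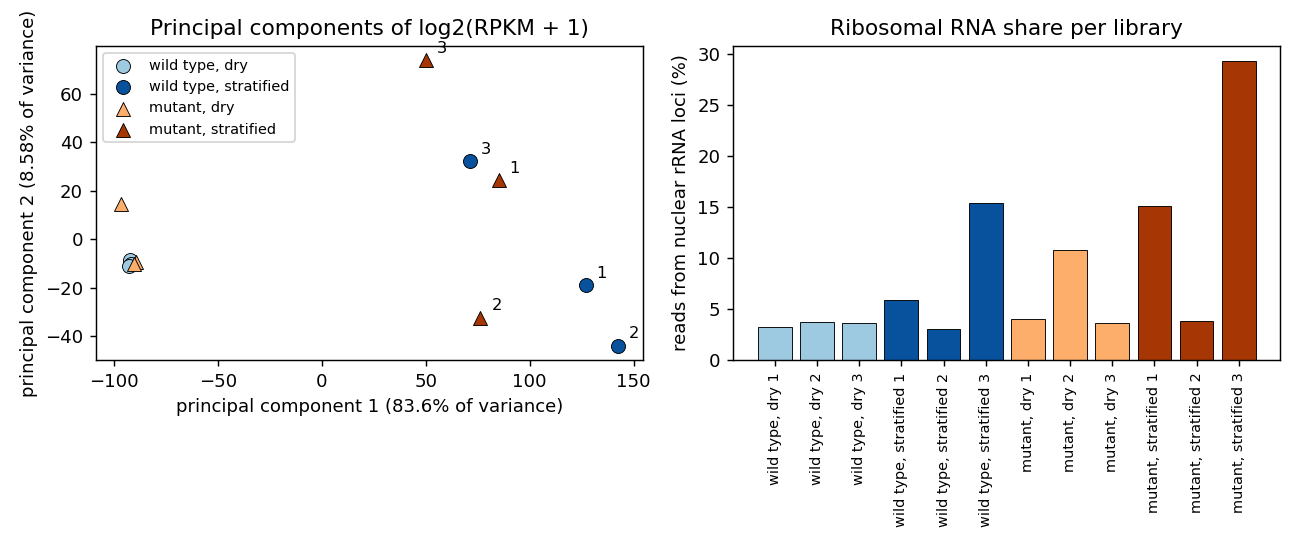
Left, the 12 libraries on the first 2 principal components of log2(RPKM + 1), with stratified libraries numbered by replicate; right, the percentage of reads from nuclear ribosomal RNA loci in each library. Dry libraries lie together, wild-type stratified library 3 at 71.5 lies among the mutant-labelled stratified libraries, and 4 libraries exceed 10% ribosomal RNA.

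The targeted loci were examined first as a check of the genotype labels. Neither the table nor the reference pairs the names ALKBH1A and ALKBH1B with loci, so the loci were those entered before the data were examined. AT1G11780, entered as ALKBH1A, was detected in every library, at 4.50 ± 0.0656 RPKM (SD, n = 3) in dry and 13.0 ± 2.07 in stratified wild-type seeds, against 5.55 ± 1.11 and 10.5 ± 4.04 in mutant-labelled seeds. The genotypes differed there by a log2 change of 0.24 ± 0.28 (SE) in dry seeds (limma adjusted p = 1) and -0.34 ± 0.28 in stratified seeds (limma adjusted p = 0.535). AT3G14140, entered as ALKBH1B, had 0 to 4 reads per library, too few to compare. A further locus of the family, AT5G01780, annotated as an oxoglutarate-dependent dioxygenase on chromosome 5 from 302098 to 304279, stood at 4.65 ± 0.412 and 5.86 ± 1.35 RPKM in dry and stratified wild-type seeds. It stood at 0.226 ± 0.0548 and 0.391 ± 0.137 RPKM in mutant-labelled seeds, a log2 change of -2.20 ± 0.22 and -2.29 ± 0.22 (limma adjusted p = 9.07e-05 and 2.07e-05). Its reads numbered 166 to 319 per wild-type library and 7 to 23 per mutant-labelled library. An insertion can leave transcript outside the disrupted part, so the level of AT1G11780 neither bears out nor contradicts the label. AT5G01780 was entered beforehand as ALKBH1D, and the sources used here do not say whether it is one of the targeted loci under another name. The libraries are called mutant-labelled throughout.

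**Figure D2:**
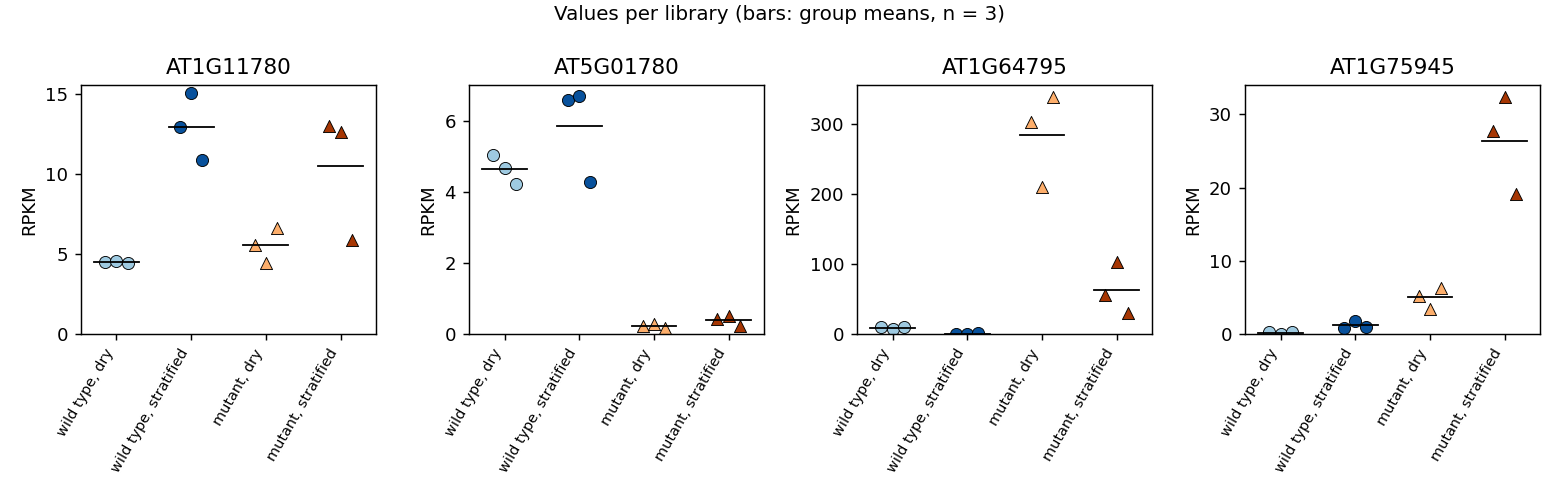
RPKM in each library of AT1G11780, AT5G01780, AT1G64795 and AT1G75945 (points, 3 libraries per group; bars, group means). AT1G11780 overlaps between genotypes, AT5G01780 averages 0.226 and 0.391 RPKM in mutant-labelled dry and stratified seeds, and AT1G64795 and AT1G75945 are higher in mutant-labelled seeds.

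After stratification of wild-type seeds camera called the lists for cell wall loosening and ribosomal proteins higher and those for desiccation tolerance, heat shock and storage lower. These 5 calls were lost with an estimated correlation (adjusted p = 0.586), and that of storage also with quantile normalization. Fry, which compares a list with no other genes, called all 5 in the same directions (highest fry adjusted p = 0.0048, for heat shock). EXPA10, an expansin, a protein that loosens cell walls, went from 0.169 ± 0.0307 to 1029.9 ± 156 RPKM (SD, n = 3), a log2 change of 9.77 ± 0.32 (SE), and EXPA1 from 0.120 ± 0.107 to 782 ± 285 RPKM. XYL1, an alpha-xylosidase that trims the wall polymer xyloglucan, rose by 7.24 ± 0.31, the uncharacterised AT5G25460 by 8.76 ± 0.27 and AT3G48140 by 7.36 ± 0.33 on the log2 scale. The carboxypeptidase SCPL44 had 0 reads in all dry libraries and reached 229 ± 148 RPKM. That mean was at least 2051-fold above a floor of 3 reads per library. The deepest falls were of JAL36, a jacalin-related lectin, from 561 ± 23.4 to 7.45 ± 5.57 RPKM, the wall enzyme XTH25 with -6.19 ± 0.59, the small heat shock protein HSP17.6A with -6.01 ± 0.67, the inositol phosphate synthase IPS2 with -5.81 ± 0.36, the asparagine synthetase ASN1 with -5.72 ± 0.46 and HSP70-5 with -5.67 ± 0.50. Each of these passed limma's test with an adjusted p of at most 5.63e-07. In all, 7535 genes rose and 2862 fell at an adjusted p under 0.05 in limma, of 15145 tested. Of these 10397 genes, 7798 changed at least 2-fold. The 72.5% of calls that were higher became 5870 higher against 5561 lower with median centring, 5905 against 5893 with TMM-style scaling and 5560 against 5750 with quantile normalization. Those scalings moved the median log2 change of all genes, 0.64, by -0.57, -0.61 and -0.65.

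All 24 cytosolic ribosomal protein genes tested rose, with a median log2 change of 3.89, 3.25 above that of all genes (camera adjusted p = 1.54e-08, against an adjusted p = 0.586 with an estimated correlation). RPL10B rose by 4.95 ± 0.32 and RPL23AB went from 20.8 ± 3.10 to 654 ± 218 RPKM. Of 18 cell wall loosening genes 16 rose and 1, EXLA1, fell by 1.02 ± 0.34, a call lost without wild-type stratified library 2 and with stratified libraries over 10% ribosomal RNA alone (list camera adjusted p = 4.8e-05, and adjusted p = 0.586 with an estimated correlation). All 12 DNA replication and cell cycle genes tested rose, among them RNR1, a subunit of ribonucleotide reductase, by 2.79 ± 0.26 and the replication clamp gene PCNA2 by 3.13 ± 0.34 (camera adjusted p = 0.00412, and adjusted p = 0.778 with an estimated correlation). These 3 lists kept their direction under every scaling. The DNA replication list was called by fry too (fry adjusted p = 0.000916).

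Of 17 genes for LEA proteins and desiccation tolerance 15 fell and 1 rose (camera adjusted p = 5.14e-08, and adjusted p = 0.586 with an estimated correlation). EM6 went from 18443 ± 1263 to 1081.7 ± 889.8 RPKM, ECP31 from 2602 ± 54.5 to 67.5 ± 55.7, and COR47, a dehydrin, rose by 2.67 ± 0.49. Of 14 heat shock genes 11 fell and 0 rose, HSP70T-2 from 176 ± 5.27 to 3.71 ± 1.73 RPKM (camera adjusted p = 4.75e-07, and adjusted p = 0.586 with an estimated correlation). Of 13 storage protein and oleosin genes 11 fell and 0 rose, with PAP85, a vicilin-like storage protein, at 14712 ± 694 and then 711 ± 753 RPKM, and the oleosin gene OLEO4 at 3041.5 ± 110 and then 238 ± 241. That call, with a camera adjusted p = 5.23e-06 and an adjusted p = 0.586 with an estimated correlation, was lost under quantile normalization too, where 7 of the 13 fell. The cruciferin CRU1 stood at 25967 ± 1267 and 6052 ± 5246 RPKM, a log2 change of -2.44 ± 0.69 (limma adjusted p = 0.00481) that no longer passed with no filter, with quantile normalization or with stratified libraries over 10% ribosomal RNA alone. The oil mobilisation list had 4 genes rising and 6 falling of 19 (camera adjusted p = 0.0474, and adjusted p = 0.839 with an estimated correlation), a call lost with fry (adjusted p = 0.516), with the replicate block, with ribosomal RNA as a factor, and without wild-type dry library 1 or 3, wild-type stratified library 1 or 3 or mutant-labelled stratified library 2. ICL, isocitrate lyase of the glyoxylate cycle, was at 2938 ± 113 and 1325 ± 418 RPKM (limma adjusted p = 0.0331). That call was lost with no filter, quantile normalization, the replicate block or stratified libraries over 10% ribosomal RNA alone, and on leaving out any 1 wild-type dry library or wild-type stratified library 1 or 2.

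Hormone genes moved in both directions. Of 21 gibberellin genes 16 rose and 3 fell, without a call for the list (camera adjusted p = 0.084, fry adjusted p = 8.01e-05, and camera adjusted p = 0.839 with an estimated correlation). GA3OX1, which makes bioactive gibberellin, had 0 reads in dry seeds and reached 15.6 ± 4.52 RPKM, at least 148-fold above a floor of 3 reads per library, and GASA6 went from 0.0854 ± 0.0230 to 163 ± 34.2 RPKM. GA3OX2 reached 14.8 ± 14.3 RPKM, a mean at least 134-fold above that floor, though its libraries varied widely. The gibberellin receptor genes GID1A and GID1C fell by 2.42 ± 0.31 and 1.85 ± 0.27. Of 31 abscisic acid (ABA) signalling genes 13 rose and 10 fell. The transcription factor gene ABI4 rose by 4.13 ± 0.31 and the receptor gene PYL4 by 4.21 ± 0.31, ABI3 rose by 1.47 ± 0.29, and ABI5 went from 177 ± 2.14 to 36.0 ± 4.31 RPKM, with limma adjusted p of at most 0.000248. Of 9 ABA metabolism genes 3 rose and 2 fell, among them NCED6 with 1.42 ± 0.24 and ABA1, zeaxanthin epoxidase of ABA synthesis, with -3.25 ± 0.30. CYP707A2, which breaks ABA down, changed by 0.91 ± 0.29 (limma adjusted p = 0.00971), a call lost under all 3 scalings, and NCED9 by 0.09 ± 0.33 (limma adjusted p = 0.823).

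The dormancy and maturation list had 5 genes rising and 4 falling of 16, with HSFA9, a seed heat shock factor, at 121 ± 3.89 and then 1.74 ± 1.38 RPKM and FUS3, a maturation regulator, at -2.18 ± 0.24. DOG1, a regulator of dormancy, stood at 16.6 ± 0.654 and 9.89 ± 10.2 RPKM, a log2 change of -1.10 ± 0.43 (limma adjusted p = 0.0301) that lost its call with no filter, in the fit of the 2 groups alone and with ribosomal RNA left out, turned to 0.37 with stratified libraries over 10% ribosomal RNA alone, and lost its call on leaving out any 1 wild-type dry library, wild-type stratified library 1 or 2, or mutant-labelled stratified library 3. Of 12 cold response genes 5 rose and 4 fell, GRP7, an RNA-binding protein, from 63.3 ± 1.70 to 1468.5 ± 236.5 RPKM. CBF3 was below the expression filter. Of 15 photosynthesis genes 8 rose and 3 fell, and the Rubisco small subunit gene RBCS1A went from 17.5 ± 0.266 to 227 ± 147 RPKM. Among 8 methylation genes the 5-methylcytosine glycosylase gene ROS1 fell by 2.50 ± 0.24, and DDM1 rose by 2.06 ± 0.29 while MET1 rose by 1.01 ± 0.27, the last lost with median centring, quantile normalization and stratified libraries over 10% ribosomal RNA alone. In the ALKBH family 3 of 7 rose, ALKBH10B by 2.66 ± 0.27 and AT1G11780 by 1.33 ± 0.28. None of these lists was called by camera (camera adjusted p of 0.084 for dormancy, 0.501 for cold response and ABA metabolism, 0.298 for ABA signalling, 0.816 for photosynthesis and the ALKBH family, and 0.535 for methylation), while fry called the ALKBH family (fry adjusted p = 0.00567). Their balance of rising and falling members shifted with scaling, to 11 and 14 for ABA signalling and 4 and 9 for dormancy with median centring. Counts adjusted over the list alone equalled those over all genes for the 15 lists in wild type. Seed coat and endosperm lists had 1 tested gene each, MUM4 with 1.00 ± 0.26 and EPR1 with -1.94 ± 0.48.

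**Figure D3:**
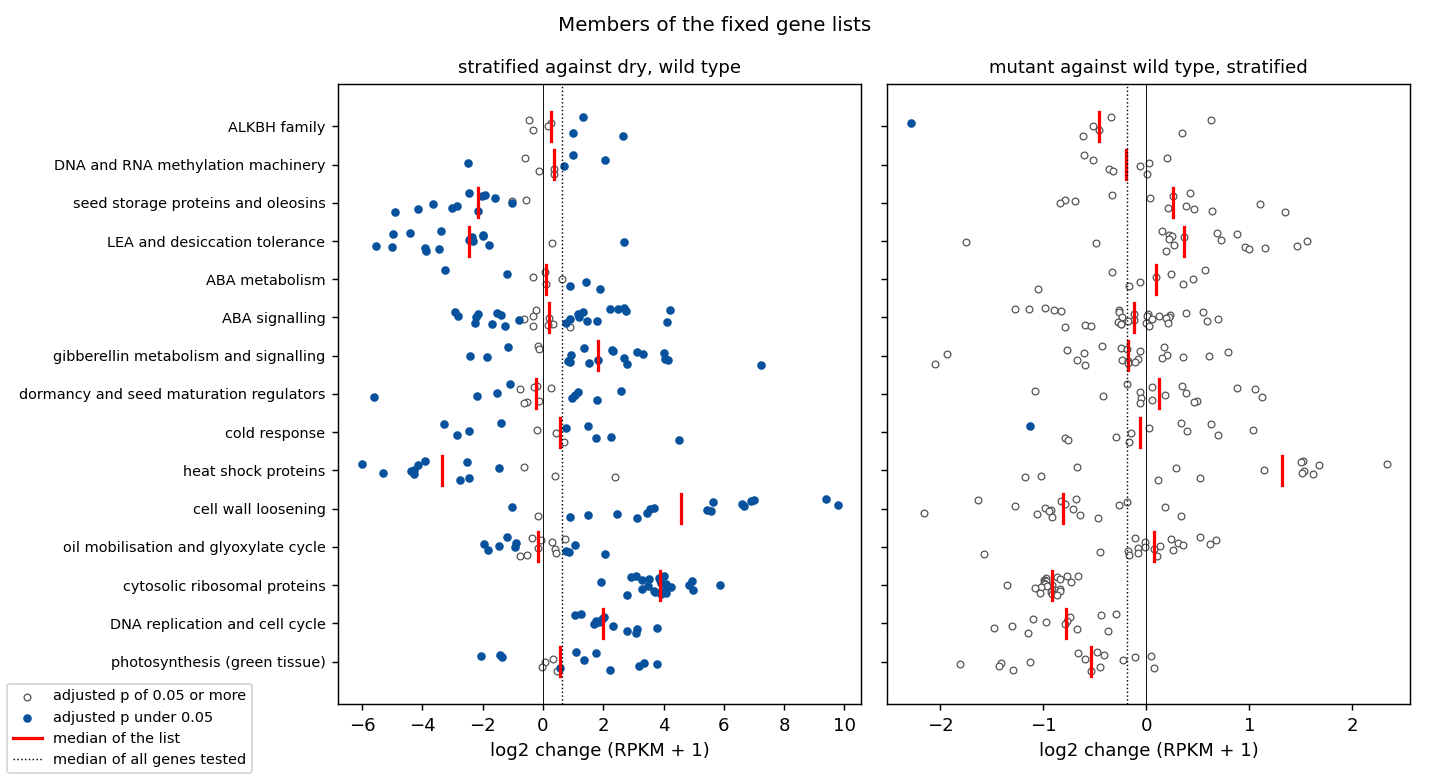
Log2 change of each tested member of the fixed gene lists (points; filled where limma's adjusted p was under 0.05), after stratification of wild-type seeds on the left and between genotypes after stratification on the right. Ribosomal protein genes lie to the right of 0 on the left panel (median 3.89) and to the left of it on the right panel (median -0.92); the dotted line marks the median of all genes.

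After stratification of mutant-labelled seeds EXPA10 went from 0.361 ± 0.0422 to 942 ± 484 RPKM (SD, n = 3), a log2 change of 9.29 ± 0.32 (SE), AT5G25460 rose by 8.93 ± 0.27, EXPA1 by 8.73 ± 0.35, XYL1 by 7.20 ± 0.31, GASA6 by 6.55 ± 0.29 and AT5G11420 by 6.48 ± 0.32. JAL36 went from 484 ± 87.5 to 19.5 ± 15.5 RPKM, and AT5G55135 at -4.33 ± 0.55, XTH25 at -4.28 ± 0.59, the beta-glucosidase BGLU19 at -4.26 ± 0.59, the oil body protein OBAP1A at -4.18 ± 0.54 and the galactinol synthase GOLS2 at -4.16 ± 0.45 were the next deepest falls. All of them had limma adjusted p of at most 1.22e-05. In all, 6567 genes rose and 2308 fell at an adjusted p under 0.05 in limma, 74.0% higher, with 6204 changed at least 2-fold and a median log2 change of 0.50. Median centring gave 4981 higher against 5121 lower, TMM-style scaling 5494 against 5370 and quantile normalization 4904 against 5300, with the median moved by -0.47, -0.46 and -0.53.

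In the mutant-labelled seeds 24 of 24 ribosomal protein genes rose (camera adjusted p = 3.54e-09), 15 of 18 cell wall loosening genes rose and 0 fell (1.46e-05), 14 of 17 LEA genes fell (3.57e-08), 10 of 14 heat shock genes fell (1.9e-06) and 13 of 13 storage genes fell (4.81e-07). With an estimated correlation all 5 of these camera calls had an adjusted p = 0.538. The LEA and storage calls were also lost with quantile normalization, under which 7 of 17 and 2 of 13 genes fell. Fry called these 5 lists and the DNA replication list (highest fry adjusted p = 0.0413, for heat shock genes). Of 12 DNA replication genes 10 rose, RNR1 by 2.48 ± 0.26 (camera adjusted p = 0.0448, and adjusted p = 0.925 with an estimated correlation), a call lost with no filter, with quantile normalization, with ribosomal RNA left out and without mutant-labelled stratified library 1 or 3. Gibberellin genes rose in 14 and fell in 3 of 21 cases, with RGA, a DELLA repressor, up by 4.25 ± 0.28 and GA3OX1 at 0.0117 ± 0.0203 and then 9.88 ± 2.50 RPKM. ABA signalling genes rose in 14 and fell in 9 of 31 cases, with ABI4 up by 4.05 ± 0.31, ABI3 up by 1.72 ± 0.29 and ABI5 at -2.07 ± 0.36. NCED6 rose by 1.76 ± 0.24 and CYP707A2 by 1.34 ± 0.29, while EM6 was at -3.61 ± 0.65 and CRU1 at -1.88 ± 0.69 (limma adjusted p = 0.000151 and 0.0272), calls lost with quantile normalization, where CRU1 turned to 0.19. That of CRU1 was also lost with no filter and without mutant-labelled dry library 1 or 3 or mutant-labelled stratified library 1 or 3. Dormancy genes rose in 6 and fell in 2 of 16 cases, with FUS3 at -3.25 ± 0.24 and HSFA9 at -4.06 ± 0.40. The remaining lists had 4 rising and 2 falling for ABA metabolism, 5 and 4 for cold response, 7 and 3 for photosynthesis, 3 and 4 for oil mobilisation, 3 and 1 for the ALKBH family and 2 and 1 for methylation. None of these was called by camera, the lowest camera adjusted p being 0.059 for gibberellin, while fry called gibberellin and the ALKBH family (fry adjusted p = 0.000129 and 0.0168). Adjusted over the list alone, 12 DNA replication genes rose, 11 heat shock genes fell, 15 ABA signalling and 15 gibberellin genes rose, 8 photosynthesis genes rose and 4 fell, and 3 oil genes fell, with the other lists as above. MUM4 and EPR1 changed by 0.82 ± 0.26 and -1.80 ± 0.48. DOG1 at -0.98 ± 0.43 (limma adjusted p = 0.0579), NCED9 at 0.66 ± 0.33 (0.0901), GA3OX2 at 1.61 ± 0.496 RPKM from 0 (0.051), at least 13.9-fold above a floor of 3 reads per library, and ICL at -0.28 ± 0.47 (0.621) did not pass. Of 29 alternatives 13 called DOG1, among them the 3 scalings and the fit of the 2 groups alone, 9 called NCED9 and 14 called GA3OX2, the latter including both pseudocounts, and the fit of the 2 groups alone called all 3. ICL was called lower with TMM-style scaling and higher with quantile normalization.

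Across the 15145 genes the changes after stratification in the 2 genotypes correlated at r = 0.950 with a slope of 0.765 for mutant-labelled on wild type, a correlation across genes, which are not independent replicates. The comparisons shared no library. Of the 10397 genes called in wild type 78.9% were also called in mutant-labelled seeds, 8200 in the same direction and 3 in opposite directions. Both lists held 6107 rising genes, where independent lists of these sizes would share 3267, and 2093 falling genes, where they would share 436. EXPA10, RNR1 and ABI4 are examples with close values in both genotypes.

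**Figure D4:**
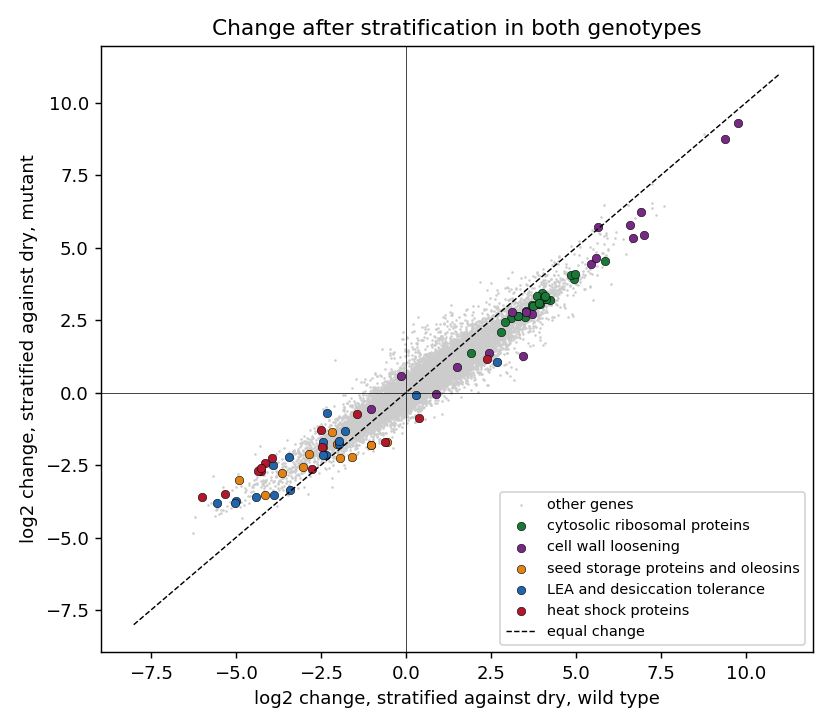
Log2 change after stratification of each of 15145 genes in wild-type (horizontal axis) and mutant-labelled seeds (vertical axis), with members of 5 fixed lists coloured and a dashed line of equal change. Points follow a line flatter than equal change, with a slope of 0.765 and r = 0.950.

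In the fit of all 12 libraries few genes were called between dry seeds of the 2 genotypes. AT1G64795, on chromosome 1 from 24082579 to 24082848, stood at 9.26 ± 1.76 RPKM in wild-type and 283 ± 66.6 in mutant-labelled seeds (SD, n = 3), a log2 change of 4.78 ± 0.37 (SE, limma adjusted p = 2.53e-06). It lies inside ILA, from 24064822 to 24083428 on the other strand, and ILA stood at 3.50 ± 0.226 and 12.4 ± 0.784 RPKM (limma adjusted p = 0.0359). The counting is not stated to use strand, so these values are uncertain. AT3G44006 was higher by 2.12 ± 0.33 and ENODL15, an early nodulin-like protein, was at 9.62 ± 1.01 and 3.07 ± 0.439 RPKM (both limma adjusted p = 0.0139). With a pseudocount of 0.1 the calls of ENODL15 and AT3G44006 were lost, with median centring that of ENODL15, and with no filter those of AT3G44006 and ILA. The calls of ENODL15 and ILA were lost on leaving out any 1 dry library, that of ILA also without wild-type or mutant-labelled stratified library 1, and that of AT3G44006 on leaving out any 1 dry library except mutant-labelled library 2. With AT5G01780 and with AT1G75945 at 2.33 and AT4G34071 at -1.11, 2 loci outside the naming rule that were named after their values were seen, 7 genes passed limma's adjusted p of 0.05, 4 higher and 3 lower, and 227 had an unadjusted p under 0.05. Those 227 are a smaller share of the 15145 genes tested than the 0.05 that chance alone would give. They are therefore no sign of further differences.

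A fit of the 2 dry groups alone called 30 genes, 8 higher and 22 lower. In the fit of all 12 libraries the count of 7 fell to 3 without any 1 wild-type dry library or without mutant-labelled dry library 1 or 3, to 4 without mutant-labelled dry library 2, and rose to 18 without wild-type stratified library 3. Among the regulators fixed beforehand, DOG1 differed by -0.31 ± 0.43, ABI3 by -0.44 ± 0.29, ABI5 by -0.20 ± 0.36, NCED6 by -0.40 ± 0.24, NCED9 by -0.22 ± 0.33 and CYP707A2 by -0.60 ± 0.29, and CRU1, EM6 and ICL by -0.14 ± 0.69, -0.10 ± 0.65 and -0.38 ± 0.47, each with a limma adjusted p = 1. These SEs come from a spread pooled over dry and stratified libraries, not from the dry libraries alone. On simulated data this fit recovered 29% of genes changed by a log2 of 1 in dry seeds, with 1 false call. A fit of the 2 dry groups alone recovered 79%, with 7 false calls. The lack of a call is therefore no evidence of equal levels. GA3OX2 had 0 reads in all dry libraries, as GA3OX1 had in the wild-type ones. Of the lists, ABA signalling was lower with a median of -0.20 (camera adjusted p = 0.0188, and adjusted p = 0.942 with an estimated correlation), although 0 of its 31 genes passed in limma over all genes or adjusted over the list alone. Fry gave it an adjusted p = 0.951, and the call was also lost with ribosomal RNA as a factor and without mutant-labelled dry library 1 or mutant-labelled stratified library 3. The other lists held 0 called genes, except the ALKBH family with AT5G01780 under both adjustments.

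After stratification, mutant-labelled seeds had higher levels of AT1G64795, AT1G75945 and BGLU30 and lower levels of GPT2, GSTU25 and AT5G05365 than wild-type seeds. BGLU30, a beta-glucosidase, stood at 2.91 ± 2.01 RPKM in wild-type and 28.6 ± 9.16 in mutant-labelled seeds (SD, n = 3), AT1G75945 at 1.21 ± 0.533 and 26.4 ± 6.69, and AT1G64795 at 0, 0.465 and 0.884 in wild-type libraries 1, 2 and 3 and 62.9 ± 36.6 in mutant-labelled ones. GPT2, a plastid glucose 6-phosphate translocator, stood at 113 ± 39.1 and 20.5 ± 10.3, the glutathione transferase GSTU25 at 8.60 ± 2.21 and 0.766 ± 0.242, and AT5G05365, a heavy metal transport family protein, at 16.7 ± 5.33 and 2.35 ± 1.07 RPKM. The log2 differences were 3.05 ± 0.36, 3.63 ± 0.28, 5.34 ± 0.37, -2.45 ± 0.32, -2.43 ± 0.22 and -2.40 ± 0.26 in that order, with limma adjusted p of at most 0.000675. HSP70-5 at 2.70 ± 0.50 and AT3G06345 at 2.31 ± 0.38 were higher, and AT4G29030 at -2.30 ± 0.45, SCPL20 at -2.26 ± 0.46 and the cold-inducible KIN2 at -1.13 ± 0.22 were lower, with limma adjusted p from 0.0103 to 0.0493. These 5 calls were lost without wild-type stratified library 1, and those of HSP70-5, AT4G29030, SCPL20 and KIN2 also without wild-type stratified library 2 or any 1 mutant-labelled stratified library. Those of SCPL20 and KIN2 were lost without any 1 dry library and that of AT4G29030 without any 1 mutant-labelled dry library. With a pseudocount of 0.1, a model without trend and voom the calls of AT4G29030, SCPL20 and KIN2 were lost, with no filter those of HSP70-5, AT4G29030 and SCPL20, with median centring those of AT4G29030 and KIN2, and with a robust variance model and with ribosomal RNA left out those of AT4G29030 and SCPL20. Among stratified libraries over 10% ribosomal RNA alone those of HSP70-5 and AT4G29030 were lost.

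**Figure D5:**
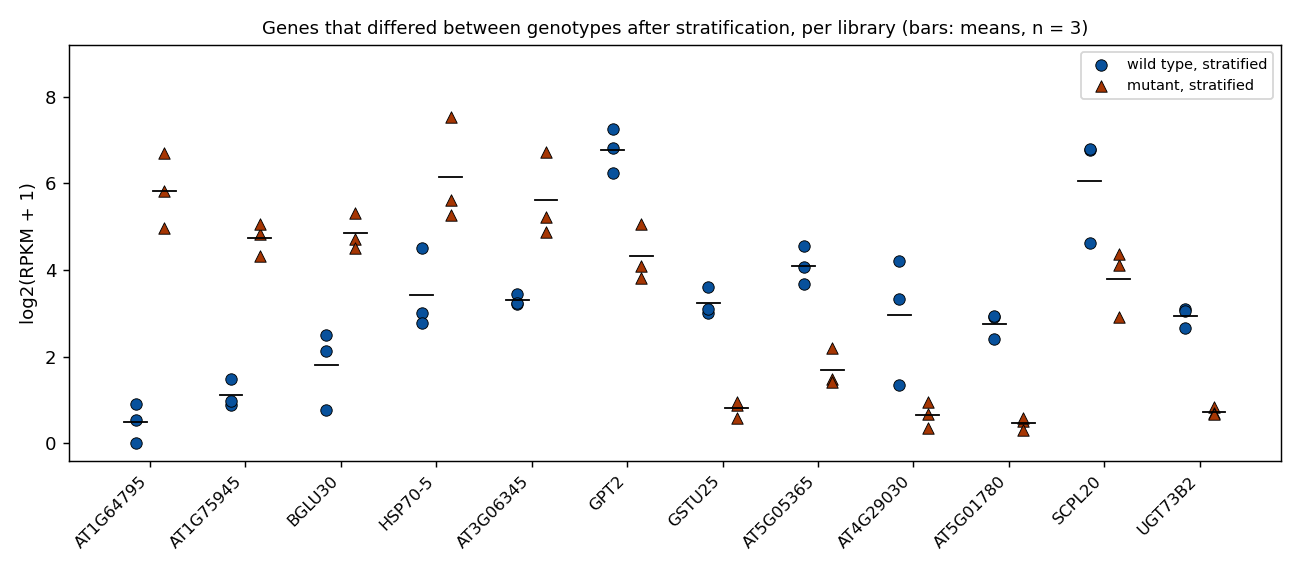
Log2(RPKM + 1) in each stratified library of genes that differed between genotypes (circles, wild type; triangles, mutant-labelled; bars, means of 3 libraries). BGLU30 averages 2.91 RPKM in wild-type and 28.6 in mutant-labelled seeds, and GSTU25 8.60 and 0.766.

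In all, 32 genes differed at an adjusted p under 0.05 in limma, 6 higher and 26 lower in mutant-labelled seeds, and 2799 had an unadjusted p under 0.05. The calls were 50 higher and 66 lower with median centring, 79 and 94 with TMM-style scaling and 151 and 162 with quantile normalization, which moved the median log2 difference of all genes, -0.19, by 0.18, 0.20 and 0.19. The count of 32 became 4505 without wild-type stratified library 3, 12, 16 and 15 without wild-type stratified library 1, wild-type stratified library 2 and mutant-labelled stratified library 3, and 21, 20 and 21 without mutant-labelled dry library 1, 2 and 3. On simulated data with 200 genes changed this comparison gave 157 false calls among 15145 genes, so its count is not well calibrated. A fit of the stratified groups alone gave 2 false calls there and, on the real data, called 145 genes, 48 higher and 97 lower. With ribosomal RNA over 10% as a factor, chosen after seeing the data, 103 genes were called. Other fits chosen then leave 1 stratified library in a genotype, so they rest on that library. Omitting the 4 libraries above 10%, or taking stratified libraries under 10% alone, leaves 1 mutant-labelled stratified library. Taking stratified libraries over 10% alone leaves 1 wild-type stratified library. DOG1 differed by -0.19 ± 0.43, ABI3 by -0.18 ± 0.29, ABI5 by 0.00 ± 0.36, NCED6 by -0.06 ± 0.24, NCED9 by 0.35 ± 0.33, CYP707A2 by -0.17 ± 0.29, GA3OX1 by -0.60 ± 0.25, GA3OX2 by -1.94 ± 0.58, CRU1 by 0.42 ± 0.69, EM6 by 0.68 ± 0.65 and ICL by 0.53 ± 0.47. None of these 11 passed, the lowest limma adjusted p being 0.152. GA3OX2 was called lower in the fit of the 2 groups alone and with the replicate block, and without wild-type stratified library 3 GA3OX1, GA3OX2 and EM6 were called. With the 4 libraries above 10% ribosomal RNA left out ABI3, ABI5, NCED9, GA3OX1, GA3OX2, CRU1, EM6 and ICL were called, and ABI3 changed direction. Among stratified libraries over 10% alone DOG1 was called. The calls of these fits rest on 1 mutant-labelled and on 1 wild-type stratified library, in that order.

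Of the lists, ribosomal protein genes were lower in mutant-labelled than in wild-type stratified seeds with a median of -0.92 (camera adjusted p = 3.68e-08), DNA replication genes with -0.78 (0.000382), photosynthesis genes with -0.54 (0.0063) and cell wall loosening genes with -0.81 (0.00887). Relative to all other genes, heat shock genes were higher with 1.32 (camera adjusted p = 6.53e-07) and LEA genes with 0.37 (0.000429). So were dormancy genes with 0.12 (camera adjusted p = 0.00508) and oil mobilisation genes with 0.08 (0.0306). The median of all genes was -0.19, so the dormancy and oil mobilisation calls do not by themselves show higher levels. With an estimated correlation all 8 lists had an adjusted p = 0.757, and fry called 0 of them. No member of these lists passed limma over all genes. Adjusted over the list alone, 23 ribosomal protein genes, 5 DNA replication genes, 5 photosynthesis genes and 1 LEA gene were lower and 6 heat shock genes higher, as were 3 gibberellin genes, 1 ABA metabolism gene and 1 ABA signalling gene on the lower side. Ribosomal RNA exceeded 10% in 2 of 3 mutant-labelled and 1 of 3 wild-type stratified libraries, beside each of these lists. Without wild-type stratified library 1 the calls of dormancy, cell wall, oil mobilisation and photosynthesis genes were lost and 4 lists remained. That of cell wall genes was also lost with quantile normalization. That of oil mobilisation was also lost without wild-type stratified library 2 or 3 or mutant-labelled stratified library 2, and that of photosynthesis without mutant-labelled stratified library 1.

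For a difference between genotypes in the response to stratification itself, limma called 4 genes. Simulated data with 200 genes changed gave 15 false calls for this comparison, so these calls are uncertain. No run without changed genes was made, so the count of 4 cannot be set directly against the count of 15. BGLU30 went from 13.6 ± 0.497 to 2.91 ± 2.01 RPKM in wild-type seeds and from 12.3 ± 2.22 to 28.6 ± 9.16 in mutant-labelled seeds (SD, n = 3), a difference of 3.19 ± 0.51 (SE) in log2 change (limma adjusted p = 0.0239). GSTU25 and AT5G05365 had 0 reads in all dry libraries and rose less in mutant-labelled seeds, by -2.43 ± 0.30 and -2.40 ± 0.37 (limma adjusted p = 0.00285 and 0.0215). UGT73B2, a flavonoid glucosyltransferase, reached 6.79 ± 1.24 RPKM in wild-type and 0.667 ± 0.103 in mutant-labelled seeds, a difference of -2.20 ± 0.28 (limma adjusted p = 0.00285). At an unadjusted p under 0.05 there were 1058 genes. All 4 calls were lost with a pseudocount of 0.1 and with voom on the recovered reads, which called 0 genes each, with 974 and 1338 at an unadjusted p under 0.05; that of BGLU30 was also lost with no filter, median centring, quantile normalization and ribosomal RNA left out, that of AT5G05365 with no filter and that of UGT73B2 with median centring. Those of BGLU30 and AT5G05365 were lost without any 1 dry library or without mutant-labelled stratified library 2 or 3, and that of BGLU30 without mutant-labelled stratified library 1. The count was 2342 without wild-type stratified library 3 and 2 without any 1 dry library or without mutant-labelled stratified library 2 or 3. The 11 regulators fixed beforehand that passed the expression filter gave no call, the lowest limma adjusted p being 0.671. GA3OX2 was called without wild-type stratified library 3. By fits chosen after seeing the data, with the 4 libraries above 10% ribosomal RNA left out ABI3, ABI5, NCED9, CYP707A2, GA3OX1, GA3OX2, CRU1, EM6 and ICL were called, and without both stratified libraries numbered 3 these except ABI5, and DOG1. The first of these fits holds 1 mutant-labelled stratified library, so its calls rest on that library.

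Of the lists, the difference in response was negative for ribosomal protein genes with a median of -0.76 (camera adjusted p = 1.57e-05), DNA replication genes with -0.76 (0.000462) and cell wall loosening genes with -0.79 (0.0132). It was positive for heat shock genes with 1.39 (5.92e-05), LEA genes with 0.48 (0.00457), dormancy genes with 0.42 (0.00457) and oil mobilisation genes with 0.24 (0.00967). With an estimated correlation all 7 had an adjusted p = 0.757, and with fry 0.836. The LEA call was lost with median centring and TMM-style scaling and the cell wall call with quantile normalization and no filter. Without wild-type stratified library 1, 2 or 3 the cell wall, LEA or oil mobilisation call, in that order, was lost. No list member passed over all genes, and 1 cold response gene was lower adjusted over the list alone. The log2 changes between genotypes in dry and in stratified seeds correlated at r = -0.04 across genes, and 3 genes, AT1G64795, AT1G75945 and AT5G01780, were called in both in the same direction.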

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

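The tests on other splits of the libraries, on wild-type stratified library 3, on genes with few reads and on ILA were chosen only after the result was seen; the bounds of the test on a few genes taking most of the reads were set before its value was computed.

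For a difference between the genotypes in the response to stratification, limma's interaction term called 4 genes and camera 7 gene lists. All 7 camera list calls were lost with an estimated correlation (adjusted p = 0.757) and with fry (0.836). Simulated data with 200 genes changed gave 15 false calls for this term. For GSTU25, AT5G05365 and UGT73B2 the log2 change in mutant-labelled minus that in wild-type seeds was -2.43, -2.40 and -2.20, and for BGLU30, which fell in wild-type and rose in mutant-labelled seeds, it was 3.19. Of 100 splits of the libraries, the real one included, 14 called at least 4 genes and the highest other called 2707. Each of those others divided the stratified libraries by genotype, or as wild-type 1 and 2 and mutant-labelled 2 against the rest. They carry the genotype difference or a structure of the libraries, so the tally does not measure chance, and chance is not excluded for this count. For the genotype difference after stratification 4 of the 10 splits, the real one included, called at least the 32 genes of the real split, and the highest other called 6158, far above the real count, which points to a structure of the libraries. For stratification in wild type, stratification in mutant-labelled seeds and genotype in dry seeds, 1 of 10 splits, the real one, gave as many genes, with 10397, 8875 and 7 calls against 0 in the highest other, and 10 splits are too few for a share under 0.05.

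Wild-type stratified library 3 lay nearer to the mutant-labelled stratified libraries, with r of 0.953 to 0.985, than to libraries 1 and 2 of its own group, with 0.916 and 0.890. A mislabelled sample is argued against by the loci that separate the genotypes, since at 3 of 5 (AT5G01780, AT1G64795 and AT1G75945) this library lay 4-fold or more outside the mutant-labelled range on the wild-type side; this bound replaced an earlier one, a minimum share of loci nearer the wild-type level, after that one had given 3 of 5, with AT2G12400 and AT3G44006 nearer the mutant-labelled level, and had left the question undecided. RNA of dry seeds mixed into the sample would need the shares of dry and of stratified RNA to add up to about 1, and they added up to 0.327, from 0.276 (quartiles 0.170 to 0.427) over 280 genes absent from dry seeds and 0.0516 (0.0294 to 0.0846) over 60 genes low after stratification. A library difference that goes with the ribosomal RNA share stays open and cannot be told apart from seeds of a lesser response, because the split of wild-type 1 and 2 and mutant-labelled 2 against the rest, which follows that share, called 6158 genes, while mutant-labelled library 2, low in ribosomal RNA, lay at 76.4 on the first component and not with the wild-type libraries at 127 and 143. Within libraries under 10% ribosomal RNA the genotype comparison called 5426 genes with 1 mutant-labelled library, and within those over 10% it called 128 with 1 wild-type library.

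More genes were called higher than lower after stratification in wild-type seeds, 72.5% of calls. Whether genes with few reads in dry seeds account for the excess stays undecided. Among genes with a mean of at least 5 RPKM, 66.2% of calls were higher. That mean takes in stratified as well as dry libraries, so genes with few reads in dry seeds can pass it by rising. SCPL20, at 0.015 RPKM in dry and 80.4 RPKM in stratified wild-type seeds, is an example. The test therefore does not remove the genes in question. A few genes taking most of the reads may account for most of the excess. Without the 50 highest loci and ribosomal RNA, and with the rest rescaled to the same total, 53.9% of calls were higher in wild-type seeds. That was 6441 higher and 5500 lower of 16000 genes tested, against 7535 and 2862 of 15145, so the share fell mainly through more lower calls. In mutant-labelled seeds 56.9% were higher. In wild-type seeds the rescaling lowers all remaining genes of stratified libraries against dry ones, so a lower share follows from the scaling itself. The reads outside those loci made up 49.8% to 50.3% in wild-type dry libraries and 86.0%, 91.6% and 62.5% in stratified libraries 1, 2 and 3. Whether the total mRNA per seed also rose was not measured, so a biological share of the excess stays untested.

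ILA and AT1G64795, which overlap on opposite strands with 142 of the 201 exon bases of AT1G64795 shared, were both higher in mutant-labelled dry seeds. The same reads counted for both genes would give ILA no more added reads than AT1G64795, and ILA gained up to 1.73 reads per read gained at AT1G64795, in library 2, so the lowest ratio, 1.21 in library 3, argues against shared reads as the whole cause. Part of the gain at ILA may still be shared, since the use of strand in counting is not given in the sources used here. The ratio covers only reads counted for both genes. It cannot tell whether reads from the strand of AT1G64795 were counted for ILA alone. A difference between the genotypes at this locus, a biological explanation or a consequence of how the line was made, stays open and untested.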

How the results depend on the processing

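The ribosomal RNA, voom and omission tests, with the exception of single libraries left out, were chosen only after the result was seen. The counts for stratification stayed within 1.5 times the reported ones except with a mean of at least 5 RPKM, which tests fewer genes and gave 6121 in wild type and 5444 in mutant-labelled seeds, and ranged over left-out libraries from 9298 to 11396 and 7217 to 10062. Counts for genotype in dry seeds, genotype in stratified seeds and the interaction, reported as 7, 32 and 4, were 4, 18 and 0 with a pseudocount of 0.1 and 4, 10 and 1 with a mean of at least 5 RPKM. TMM-style scaling gave 29, 173 and 15 and quantile normalization 20, 313 and 7. Omitting the 4 libraries high in ribosomal RNA gave 44, 6420 and 5325, omitting both stratified libraries numbered 3 gave 23, 5309 and 3906, and ribosomal RNA over 10% as a factor gave 11, 103 and 9. Stratified libraries under 10% alone gave 102, 5426 and 4669 and those over 10% alone 84, 128 and 60. Fits of the groups compared alone gave 30 and 145 for the genotype contrasts. Genotype in stratified seeds and the interaction were 72 and 8 without a filter; the former was 116 with median centring and 18 without the variance trend, and the interaction was 0 with voom. At an unadjusted p under 0.05 limma had 974 interaction genes with a pseudocount of 0.1 and voom 1338. Left-out libraries gave 3 to 18, 12 to 4505 and 2 to 2342, the highest each without wild-type stratified library 3. The cause was not tested, except that fewer libraries or genes enter some of these fits.

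Replicate numbers showed no general pairing of the libraries. Of 18 pairs with the same number 2 had deviations correlated above 0.1, over a range of -0.315 to 0.197, and the own number was best in 5. Both of those 2 were between wild-type and mutant-labelled stratified libraries, at 0.172 for number 2 and 0.197 for number 3. Number 1 gave -0.232 there. A batch shared by number among stratified libraries is therefore not excluded. The replicate block moved genotype in stratified seeds to 304 and the interaction to 8. Called lists numbered 7, 6, 1, 8 and 7 over the contrasts. They were 0 in all 5 with an estimated correlation and 0 for genotype in dry seeds, genotype in stratified seeds and the interaction with fry. At an unadjusted p under 0.05 an estimated correlation gave 0 in each contrast, and fry gave 0, 2 and 0. Quantile normalization left 3 for stratification in mutant-labelled seeds, and genotype in dry seeds had 2 without both stratified libraries numbered 3 and 0 with ribosomal RNA as a factor. Left-out libraries gave 6 to 8, 5 to 7, 0 to 2, 4 to 8 and 6 to 9.

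The correlation of the changes after stratification stayed between 0.918 and 0.965 over left-out libraries, and the share of wild-type calls also called in mutant-labelled seeds between 68.0% and 86.9%. The correlation of the genotype differences, -0.0404, became 0.00404 with a pseudocount of 0.1, -0.00292 without a filter, 0.0340 with quantile normalization and -0.0857 to 0.00928 over left-out libraries, so its sign is not settled. Direction changed for CRU1 and ICL after stratification of mutant-labelled seeds with quantile normalization (0.19 and 1.55), for DOG1 after stratification of wild-type seeds with stratified libraries over 10% ribosomal RNA (0.37), and for ABI3 between genotypes after stratification without the 4 libraries high in ribosomal RNA (0.42). Of the named genes under the alternatives, 5135 results kept their side of the threshold with no called value changing sign, 177 were no longer called, 91 became called and 4 reversed. A group left with 1 library is assumed to vary like the other groups. Depth, at most 23.0 M reads, leaves AT3G14140, with at most 4 reads per library, undecided.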

Other observations

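Groups defined by words in the gene descriptions, and the test of how far the libraries stood along the change from dry to stratified seeds, were chosen only after the result was seen.

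In 5 groups, of proteasome, tubulin, chaperonin, 50S and 30S ribosomal and tRNA genes, more genes rose than fell after stratification in both genotypes, and their camera calls were lost with an estimated correlation (adjusted p = 0.709 in wild-type and 0.669 in mutant-labelled seeds). Of 54 proteasome genes 44 rose and 2 fell in wild-type and 49 rose and 1 fell in mutant-labelled seeds, with median log2 changes of 1.42 and 1.61. Of 25 tubulin genes 22 and 18 rose, of 21 chaperonin genes 19 rose and 2 fell in each genotype, and of 59 genes for 50S and 30S ribosomal proteins 45 and 50 rose and 1 fell in each. Of 116 genes with tRNA in their description, among them aminoacyl-tRNA synthetases, 100 and 74 rose and 3 fell in each. In each of these groups more genes rose than fell with median centring, TMM-style scaling and quantile normalization too. Camera called all 5 (highest adjusted p = 0.00112 in wild-type and 0.00399 in mutant-labelled seeds). Fry called all 5 too (highest fry adjusted p = 0.00175 in wild-type and 0.00433 in mutant-labelled seeds).

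Genes for pentatricopeptide repeat proteins, which act on organelle RNA, rose in 269 and fell in 11 of 380 cases in wild-type and rose in 252 and fell in 7 in mutant-labelled seeds, with a median of 0.84 and 0.79 against 0.64 and 0.50 for all genes. Camera called this group up (adjusted p = 0.000345 and 2.66e-05), a call lost with an estimated correlation (0.709 and 0.669). Fry called it in both genotypes (fry adjusted p = 0.000884 and 0.00148). With quantile normalization the wild-type counts were 116 and 69. Of 60 cytochrome P450 genes 16 rose and 25 fell in wild-type seeds, and of 31 UDP-glycosyltransferase genes 10 rose and 18 fell. Their camera adjusted p was 0.000294 and 0.000786, and the adjusted p = 0.709 for both with an estimated correlation. Neither was called by fry (fry adjusted p = 0.285 and 0.201). In mutant-labelled seeds 15 rose and 17 fell, and 9 rose and 9 fell. Under the 3 scalings more genes fell than rose in both groups and both genotypes. Camera called neither peroxidase nor glutathione transferase genes in either genotype, while fry called peroxidases in both (adjusted p = 0.0025 and 0.0192). Of 25 peroxidase genes 16 rose and 6 fell in wild-type seeds. Of 34 glutathione transferase genes 15 rose and 7 fell there, which became 12 and 14 with median centring, 12 and 16 with TMM-style scaling and 11 and 16 with quantile normalization. Between the genotypes and for the interaction camera called some of the 10 groups, and neither fry nor an estimated correlation called any.

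A hypothesis is that the mutant-labelled libraries stand less far along the dry-to-stratified change. It predicts that the genotype difference after stratification runs against the wild-type change across genes, taken from different wild-type libraries, for every choice of library. The correlation across genes was -0.611, -0.657 and -0.415 with the change taken from wild-type stratified library 1, 2 and 3, so the highest, -0.415, is in line with it. Wild-type stratified library 3 compared with libraries 1 and 2 of its own group gave -0.646 and -0.600, so a like difference arises within the wild type and cannot be assigned to genotype from these libraries.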
